A study of Mus musculus with 14 samples.

How the data were processed

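Messenger RNA was measured in material captured as primitive erythroid precursors, the first red cell precursors of the mouse embryo, taken from the yolk sac at embryonic day 9.5. Per the labels' protocols, yolk sacs were frozen, 8 µm sections were stained, and erythroid cells were captured by laser microdissection and inspected by eye. Each biological replicate held 2 to 4 yolk sacs from 2 litters, and whether replicates shared a litter is not given in the sources used here. Total RNA of 10 to 20 ng per sample was amplified in a 2-cycle reaction primed at the poly(A) tail and hybridised to Affymetrix mouse expression arrays, 1 array per sample. Such priming enriches the 3′ ends of transcripts, and the small input makes the yield of each transcript depend on RNA quality.

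The deposited table holds log2 expression values per probe set, a set of short probes for 1 transcript. The submitters' processing notes name GCOS, RMA, affy and limma, with no versions. RMA subtracts background, normalizes between arrays and summarises the probes of a set on the log2 scale. It compresses differences between weak signals, and normalization between arrays hides a change shared by most genes. The values ran from 3.29 to 14.7, array medians from 6.55 to 6.67 and interquartile ranges from 2.31 to 3.12, so the arrays do not share a distribution. The deposited log2 values were used as they are, and further normalization was an alternative. No array was a copy of another, and no column lay outside the 14 samples.

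Of 22690 probe sets, 64 were controls. The platform annotation paired 20380 with 1 gene, 691 with several and 1555 with none, the controls left out. Gene identifiers of 20351 probe sets were found in the RefSeq gene table of assembly GRCm38.p6, and 0 symbols changed through it. The values carry no genome build, so no coordinates are given, and that table served only for names and for which genes are neighbours. Each of the 12393 genes was represented by its brightest probe set, the one with the highest mean over the 14 arrays. No filter on dim genes was applied in the reported results. Precision is limited by the number of arrays: 8 wild-type, 3 KLF1-/- and 3 labelled KLF1-/- KLF2-/-.

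Groups were taken from the sample titles. One linear model with a mean per genotype was fitted to all 14 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), so that the groups share an estimate of the spread. P-values were adjusted over all genes by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. The contrasts were KLF1-/- minus wild type, KLF1-/- KLF2-/- minus wild type, and KLF1-/- KLF2-/- minus KLF1-/-. Every adjusted p below comes from limma unless another test is named. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9, and statmod 1.5.0 was loaded for limma.

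The titles are numbered in 2 runs. Numbers 1 to 8 hold 4 wild-type arrays and the KLF1-/- arrays, and numbers 9 to 15 hold 4 wild-type arrays and those labelled KLF1-/- KLF2-/-. The labels do not say whether these number runs are batches. The number run was to enter the model as a block if at least 1% of genes (124) were called between wild-type arrays 1 to 4 and 9 to 12. In limma, 0 were called, with 928 at an unadjusted p under 0.05 where chance gives 620, and the smallest adjusted p was 0.549. The model therefore has no block, and the fit with it is an alternative.

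There were 32 gene lists with 701 members, 612 of them measured, covering erythroid functions, the cell cycle, Myc targets, stress responses and markers of other yolk sac cells. They were tested with camera, in limma, which asks whether a list shifts relative to all other genes, with a preset correlation between genes of 0.01 and adjustment over the 32 lists of a comparison. Camera with a correlation estimated from the arrays, and fry, which asks whether a list's genes move on balance one way, were run beside it. A list's mean is the mean log2 difference of its measured members. List scores per array, the mean of the members' log2 values, were compared between groups by exact two-sided permutation tests.

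Genes were named by a rule: Klf1, Klf2 and Myc; in each comparison up to 8 called genes per direction with the largest change whose mutant arrays all lie on one side of the wild-type arrays of their own number run, a condition not applied between the mutant genotypes; and of each list up to 4 called members, or the 2 with the smallest p where none was called. For the last part, members are named only for lists that passed camera. Add2, Cd24a, Dmtn, Ermap, Gp5, Hhex, Pf4, Rhd, Slc4a1 and Steap3, which passed when adjusted over their list alone, and the list members Afp and Ttr were chosen after their values were seen. The limma, camera and fry tests, the correlation of the mutant changes, the lists, the naming rule and all alternatives but those named below as added later were fixed before the data were examined. The permutation tests of list scores, the principal components and their relations to array measures were chosen afterwards.

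The fit was checked on simulated data with 12393 genes, independent noise and no spread shared by an array's genes. In the simulated KLF1-/- comparison, 98%, 70%, 64% and 100% of 50 genes changed by −2, −1, 1 and 2 were called, with 5 false calls. In the simulated KLF1-/- KLF2-/- comparison the shares were 98%, 78%, 78% and 96%, with 14 false calls. A list of 20 genes shifted by 0.5 gave a camera p of 1.98e-16 and an unchanged list 0.949.

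Alternatives changed the number run block, the choice of probe sets, a filter on dim genes, the normalization, the variance model, array weights, a Gapdh covariate for RNA quality and the arrays in the fit, each array being left out in turn. Added after the data were examined were fits with the first 2 principal components as covariates, without the arrays at the ends of the first component, with normalization and the block together, and with a strong prior on array weights; also, for lists and named genes, quantile normalization again, and for named genes, 1 number run alone. A probe set that the annotation pairs with no gene was left out of all comparisons of genes.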

Results

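Expression was profiled in material laser-captured as primitive erythroid precursors from E9.5 mouse yolk sacs, all labelled as strain FVB/N. Such precursors are nucleated and enter the circulation before definitive red cells form. There were 8 wild-type samples, 3 lacking KLF1 and 3 labelled as lacking both KLF1 and KLF2. KLF1 and KLF2 are zinc finger transcription factors of the Krüppel-like family, and KLF1 is a major activator of red cell genes. The series asks which genes depend on KLF1, and on both factors, at this stage, and its title names c-myc as part of the same network. The erythroid genes Hbb-y, an embryonic beta-like globin, and Slc4a1, the band 3 anion exchanger, were bright in wild type, at 14.42 ± 0.11 and 12.25 ± 0.47 (log2 expression, mean ± SD, n = 8). Markers of other cells were bright there too: Apoa1 of visceral endoderm at 11.46 ± 0.98, Lum of mesenchyme at 11.24 ± 0.40 and the platelet gene Pf4 at 11.21 ± 0.37. The captured material therefore held transcripts that mark other cells. These values do not measure what share of the RNA came from erythroid cells.

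Klf1 signal was lower on every mutant array than on every wild-type array. It was 10.67 ± 0.63 in wild type (SD, n = 8), 9.45 ± 0.39 in KLF1-/- (n = 3) and 9.15 ± 0.53 in the arrays labelled KLF1-/- KLF2-/- (n = 3). Its log2 change was −1.22 in KLF1-/- (adjusted p = 0.9998 over all genes, 0.0449 adjusted over the list alone) and −1.52 in KLF1-/- KLF2-/- (0.317, and 0.00798 over the list alone). With the number run as a block these were −0.78 (adjusted p = 1) and −1.96 (adjusted p = 0.0468), and the difference between the mutant genotypes was −1.18 in place of −0.30 (adjusted p = 1). Klf2 was 6.25 ± 0.25 in wild type, 6.22 ± 0.28 in KLF1-/- and 6.69 ± 0.32 in the arrays labelled KLF1-/- KLF2-/-, so it was not lower there (log2 change 0.44, adjusted p = 0.9999). Where these probe sets lie relative to the deleted parts of the genes is not given in the sources used here, so neither gene checks the labels. Myc, the gene of the transcription factor c-MYC, was 7.35 ± 0.38, 6.89 ± 0.42 and 6.46 ± 0.30 in the same order. The Myc change was −0.46 in KLF1-/- and −0.89 in KLF1-/- KLF2-/- (SE 0.236, adjusted p = 0.607, and 0.0244 adjusted over the list alone).

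**Figure D1:**
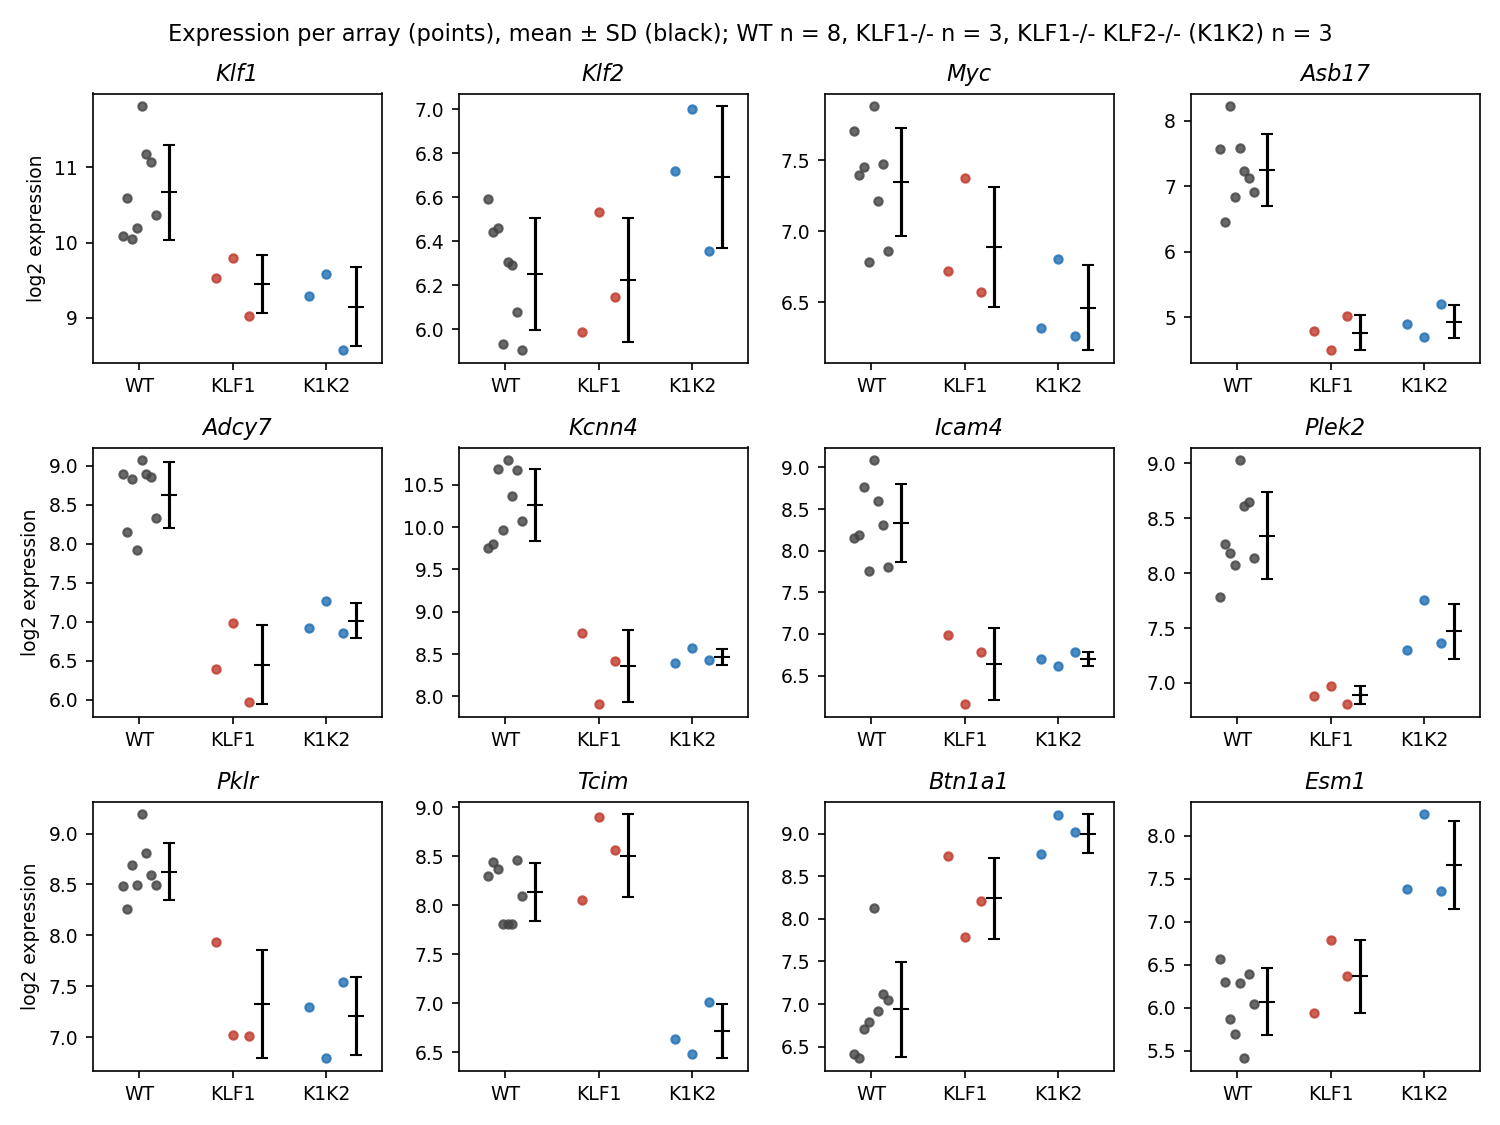
Log2 expression (vertical axes) of 12 genes on each array by genotype, with points for arrays and black marks for the mean ± SD, over 8 wild-type, 3 KLF1-/- and 3 KLF1-/- KLF2-/- (K1K2) arrays. Asb17, Adcy7, Kcnn4 and Icam4 lie lower on every mutant array than on every wild-type array, and in K1K2 Tcim is lower and Btn1a1 and Esm1 are higher than in wild type; Btn1a1 is 1.31 above wild type in KLF1-/- as well.

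The arrays differed widely within each genotype. The first principal component of the 12393 genes held 47.6% of the variance and ran from KLF1-/- replicate 6 at −47.6 to wild-type replicate 12 at 42.6. Its scores followed the interquartile range of the array's log2 values, from 2.31 to 3.12 (Pearson r = −0.973, rho = −0.934, each permutation p = 1e-05, the smallest that 100000 permutations give, adjusted p = 3e-05 over 3 relations). The range and the scores are computed from the same values, so they are not independent measures of an array. Without the 2 arrays farthest from the median range r was −0.963, and within the number runs it was −0.976 and −0.991. The excess of 3′ over 5′ Gapdh signal, a measure of RNA integrity and amplification, gave r = −0.619 (permutation p = 0.0198, adjusted 0.0298) and rho = −0.591 (p = 0.029, adjusted 0.0435). Without the 2 farthest arrays it gave −0.706, and within runs −0.511 and −0.735. The same measure for beta-actin gave r = −0.275 (permutation p = 0.343, adjusted 0.343) and rho = −0.174 (p = 0.55, adjusted 0.55), 0.0525 without the 2 farthest arrays, and −0.266 and −0.247 within runs.

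**Figure D2:**
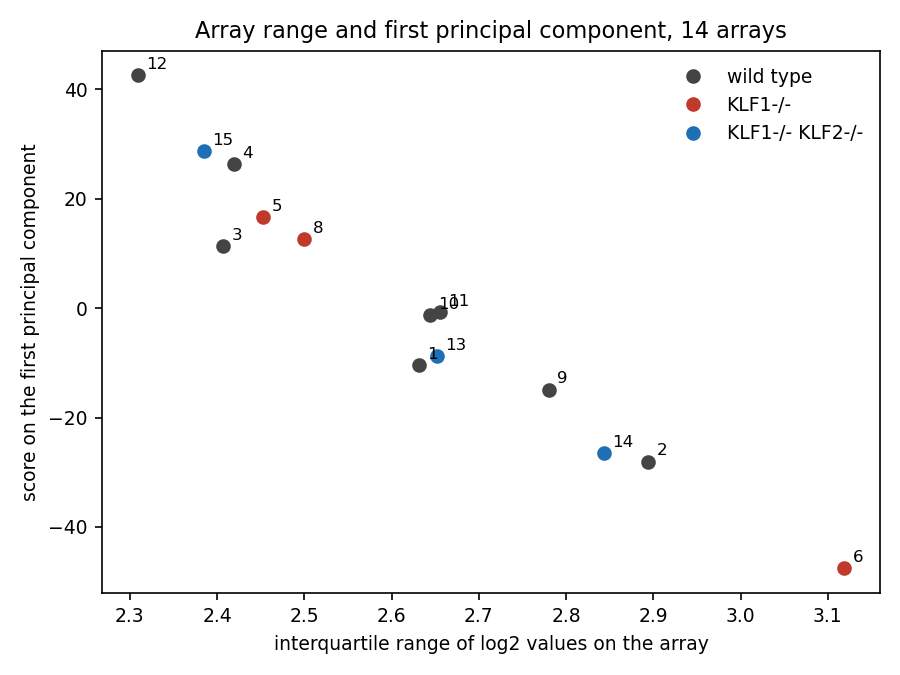
Score on the first principal component (vertical axis) against the interquartile range of the log2 values (horizontal axis) of each of the 14 arrays, coloured by genotype and numbered as in the sample titles. The scores fall as the range grows from 2.31 to 3.12 (r = −0.973), and arrays of all 3 genotypes are spread along the line.

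The KLF1-/- comparison asks which genes need KLF1 in these cells. In KLF1-/-, 5 genes were lower. Asb17, which codes for an ankyrin repeat protein with a SOCS box, fell from 7.24 ± 0.55 (SD, n = 8) to 4.77 ± 0.26 (n = 3), a log2 change of −2.47 (SE 0.285, adjusted p = 0.00337). Adcy7, an adenylyl cyclase, fell from 8.62 ± 0.42 to 6.45 ± 0.51 (log2 −2.17, SE 0.256, adjusted p = 0.00337). Kcnn4, the calcium-activated potassium channel that controls red cell volume, fell from 10.26 ± 0.42 to 8.36 ± 0.43 (log2 −1.90, SE 0.24, adjusted p = 0.00519). Icam4, the glycoprotein of the Landsteiner-Wiener blood group, changed by −1.69 (SE 0.258, adjusted p = 0.0265) and Plek2, a pleckstrin family protein of the actin cytoskeleton, by −1.46 (SE 0.213, adjusted p = 0.022). For all 5 genes every KLF1-/- array lay below every wild-type array. These were the called genes of 12393, with 0 higher. At an unadjusted p under 0.05 there were 251, 157 of them higher, where chance gives 620. The other probe sets of Adcy7 changed by −0.05 and −0.71 and that of Kcnn4 by −0.42, while Asb17, Icam4 and Plek2 have 1 probe set each. With the number run as a block 3 genes were called, and Icam4 (log2 −1.58, adjusted p = 0.166) and Plek2 (−1.19, 0.0922) were not. There was 1 call without KLF1-/- replicate 6 or 8, and there were 3 without wild-type replicate 10 or 11.

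Red cell membrane and cytoskeleton genes fell in KLF1-/- as a list. The mean over 29 of 32 members was −0.28 and the median −0.06, 12 members lay above 0, and the camera adjusted p was 1.43e-05. Adjusted p was 0.391 with an estimated correlation, and 0.156 with the number run as a block (mean −0.13). Among wild-type arrays alone, the list score was 0.289 higher in 9 to 12 than in 1 to 4 (exact permutation p = 0.0857, adjusted p = 0.914). Adjusted over the list alone, 7 members were lower: Icam4; Ermap, an erythroblast membrane protein (−2.22); Cd24a, a surface glycoprotein (−1.37); Dmtn, the actin-bundling dematin (−1.12); Slc4a1 (−0.92); Rhd, of the Rhesus blood group (−0.81); and Add2, beta-adducin (−0.36). With the block Ermap was −1.47 (adjusted p = 0.241), Dmtn −0.78 and Rhd −0.52 (adjusted p = 1 each). Iron uptake genes fell (11 of 14 members measured, 4 of the 11 above 0, mean −0.31, median −0.06, camera adjusted p = 0.0104; adjusted p = 0.464 with an estimated correlation, 0.155 with the block). Adjusted over the list alone, 3 were lower and 0 over all genes: Tfrc, the transferrin receptor (−1.50), Slc25a37, the mitochondrial iron importer (−1.27), and the ferrireductase gene Steap3 (−0.63). Other Tfrc probe sets gave −0.82 and −0.24, and dim ones of Steap3 0.03 and −0.12. Without KLF1-/- replicate 5 or 8 or wild-type replicate 9 the list's adjusted p was 0.223, 0.176 and 0.0588. With the block Slc25a37 was −0.75. The globin list passed too (6 of 7 members measured, 0 above 0, mean −0.52, median −0.05, camera adjusted p = 0.0362; adjusted p = 0.464 with an estimated correlation, 0.0587 with the block). Without KLF1-/- replicate 5 or 8 or wild-type replicate 1, 3 or 9 that p was 0.167, 0.184, 0.127, 0.123 and 0.0641. The list rested on Hbb-b2, an adult beta globin, which changed by −2.92 (SE 0.512, adjusted p = 0.0846, and 0.000287 adjusted over the list alone). The adult beta globins are near-identical copies that array probes separate poorly, and a second Hbb-b2 probe set changed by −0.55, so this value is uncertain. Hbb-y had a difference of −0.04, but its probe set lay at the ceiling of the arrays, equal to the highest value on wild-type replicates 4 and 12 and KLF1-/- replicate 5, so this does not show that Hbb-y was stable.

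Megakaryocyte and platelet genes rose in KLF1-/-. The mean over 22 of 28 members was 0.24, 18 lay above 0, 0 were called singly, and the camera adjusted p was 8.36e-05 (adjusted p = 0.0161 with an estimated correlation, fry adjusted p = 0.0857). Examples were Thbs1, thrombospondin (0.60), and Itga2b, the platelet integrin alpha chain (0.36), neither called. The mitosis list rose (20 of 21 members above 0, mean 0.23, 0 called, camera adjusted p = 0.00757; adjusted p = 0.928 with an estimated correlation), with cyclin gene Ccnb2 at 0.69 and the spindle gene Tpx2 at 0.64 (0.25 on another probe set). Without KLF1-/- replicate 6, the array at the end of the first component, its mean was −0.06, and without wild-type replicate 3 or 12 its adjusted p was 0.106 and 0.0775. With the Gapdh 3′ excess as a covariate the mitosis mean was 0.11 (adjusted p = 0.228). Macrophage and myeloid markers fell by 0.07 in the mean of 23 members (7 above 0, 0 called, camera adjusted p = 0.0239; adjusted p = 0.624 with an estimated correlation, 0.298 with the block, mean −0.03), with Cybb at −0.21 and C1qc at −0.25 (−0.39 with the block). That call ended without KLF1-/- replicate 6 or 8 or wild-type replicate 1 or 12 (adjusted p = 0.405, 0.109, 0.149 and 0.0856). Exact permutation p of the list scores per array was 0.0182 for megakaryocyte genes, 0.442 for mitosis and 0.394 for macrophage markers. It was 0.0848 for red cell membrane, 0.097 for iron and 0.0242 for globin genes. Within the run, in the same order, it was 0.0857, 0.429, 0.857, 0.286, 0.2 and 0.0857. As a measure of other cells in the capture, visceral endoderm markers had a mean of 0.11 (adjusted p = 0.388; −0.15 with the block, adjusted p = 0.09) and endothelial markers 0.09 (adjusted p = 0.279).

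**Figure D3:**
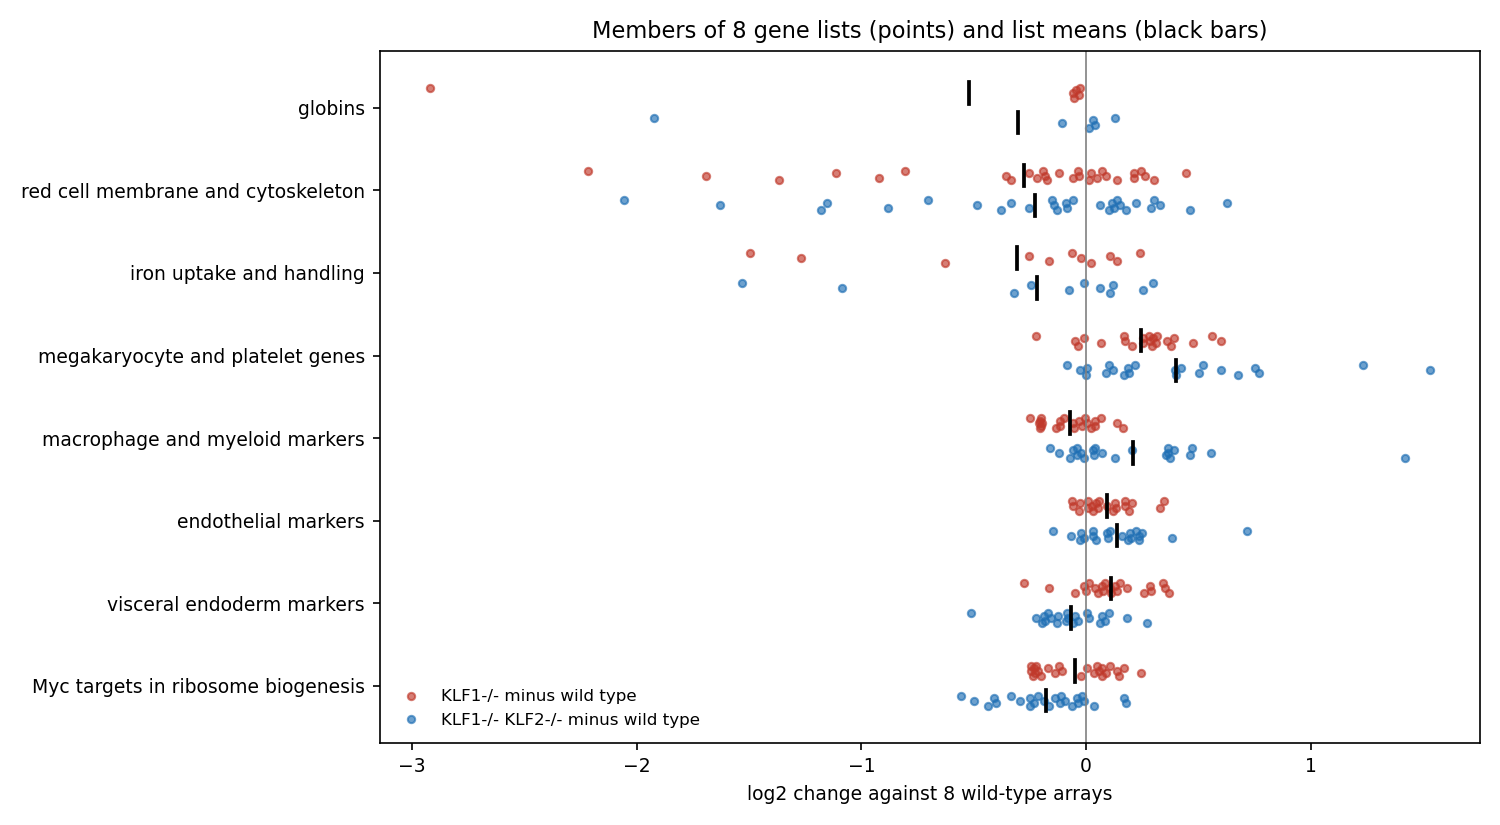
Log2 change against the 8 wild-type arrays (horizontal axis) of the members of 8 gene lists (points) in KLF1-/- and KLF1-/- KLF2-/-, with black bars for the list means. Most megakaryocyte and platelet genes lie above 0 (18 and 20 of 22), and the red cell membrane list has a tail of members below −1.

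The KLF1-/- KLF2-/- comparison asks which genes differ when both factors are lacking. In the arrays so labelled, 6 genes were lower and 2 higher than in wild type. Asb17 (log2 −2.31, SE 0.285, adjusted p = 0.0119), Kcnn4 (−1.80, SE 0.24, 0.0151), Icam4 (−1.63, SE 0.258, 0.0319) and Adcy7 (−1.61, SE 0.256, 0.0319) were lower, all 4 also called in KLF1-/-. Pklr, the pyruvate kinase of liver and red cells, fell from 8.63 ± 0.28 (SD, n = 8) to 7.21 ± 0.38 (n = 3; log2 −1.41, SE 0.226, adjusted p = 0.0319), and changed by −1.30 in KLF1-/- (adjusted p = 0.0846). Tcim, a small regulator of transcription and immune signalling, fell from 8.14 ± 0.30 to 6.71 ± 0.28 (log2 −1.42, SE 0.204, adjusted p = 0.023). Btn1a1, butyrophilin of the milk fat globule membrane, rose from 6.94 ± 0.56 to 9.004 ± 0.23 (log2 2.07, SE 0.304, adjusted p = 0.023). In KLF1-/- Btn1a1 was 8.24 ± 0.48, a log2 change of 1.31 (adjusted p = 0.454), and with the number run as a block it was 1.67 there (adjusted p = 0.101). The difference in Btn1a1 between the mutant genotypes did not pass (0.76, adjusted p = 0.9999). Esm1, a proteoglycan secreted by endothelium, rose from 6.07 ± 0.39 to 7.66 ± 0.51 (log2 1.59, SE 0.261, adjusted p = 0.0361). On all 8 genes every array labelled KLF1-/- KLF2-/- lay beyond every wild-type array. At an unadjusted p under 0.05 there were 288 genes, 199 of them higher, where chance gives 620. Plek2 changed by −0.87 (adjusted p = 0.442). Other probe sets moved less: Adcy7 −0.0011 and −0.63, Kcnn4 −0.29, Pklr −0.28 and −0.15, Btn1a1 0.16 and 0.24. With the number run as a block 4 of the 8 were called, and Icam4 (−1.75, adjusted p = 0.0539), Btn1a1 (1.70, 0.0539), Tcim (−1.33, 0.0613) and Esm1 (1.63, 0.0963) were not. Ermap (−2.81, 0.00201) and Dmtn (−1.49, 0.033) were called with the block. Without KLF1-/- KLF2-/- replicate 13 or 14 there were 0 calls in limma (194 and 171 at an unadjusted p under 0.05), without 15 there were 4, and without wild-type replicate 1, 3, 10 or 11 there were 5, 2, 3 and 4.

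Megakaryocyte and platelet genes rose in the arrays labelled KLF1-/- KLF2-/-. The mean over 22 members was 0.40, 20 lay above 0, and the camera adjusted p was 7.36e-12 (adjusted p = 0.000258 with an estimated correlation, fry adjusted p = 0.00103). Adjusted over all genes 0 members were called, and 4 over the list alone: the platelet chemokines Ppbp (1.53) and Pf4 (0.75), von Willebrand factor, Vwf (1.23), and the platelet glycoprotein Gp5 (0.40). Markers of other cells were higher as well. Macrophage and myeloid markers had a mean of 0.21 (15 of 23 above 0, 0 called, camera adjusted p = 0.00265; adjusted p = 0.313 with an estimated correlation, 0.0516 with the block), with Laptm5 at 1.42 and Tyrobp at 0.47, though other Laptm5 probe sets gave 0.04 and 0.09 and the block gave 0.80. Mesenchyme and mesothelium markers had a mean of 0.22 (19 of 23 above 0, 0 called, 0.00265; adjusted p = 0.327 with an estimated correlation), with the matrix genes Sparc at 0.65 (0.41 with the block, and −0.03 on another probe set) and Dcn at 0.50. Endothelial markers had a mean of 0.14 (16 of 21 above 0, 0 called, 0.00853; adjusted p = 0.313 with an estimated correlation), with the vascular receptor genes Flt1 at 0.20 and Flt4 at 0.24. Other probe sets gave 0.09 and −0.09 for Flt1 and −0.08 for Flt4. Visceral endoderm markers had a mean of −0.07 (camera adjusted p = 0.294), and with the block it turned to 0.20 (adjusted p = 0.0208). Without KLF1-/- KLF2-/- replicate 15 the adjusted p was 0.0665 for the macrophage and 0.0569 for the mesenchyme list, and without replicate 13 it was 0.0732 for the endothelial list. Exact permutation p of the list scores per array was 0.00606 for megakaryocyte genes, 0.0242 for macrophage, 0.139 for mesenchyme and 0.176 for endothelial markers. Within the run, in the same order, it was 0.0286, 0.0571, 0.0857 and 0.143.

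Red cell membrane genes fell again (mean −0.23, median −0.09, 13 of 29 above 0, camera adjusted p = 0.000218; adjusted p = 0.313 with an estimated correlation). With the block the mean was −0.37 (adjusted p = 2.23e-11). Adjusted over the list alone, 4 were lower: Ermap (−2.06), Icam4, Cd24a (−1.18) and Dmtn (−1.15). Tfrc changed by −1.53 and Hbb-b2 by −1.92, each lower over its list alone (adjusted p = 0.00813 and 0.0121), while the iron (mean −0.22, adjusted p = 0.141) and globin (mean −0.30, 0.294) lists did not pass. With the block the iron list passed (mean −0.30, adjusted p = 0.0208), as did the heat shock list (mean 0.24, 0.0413, against 0.18 and 0.069). Myc targets in ribosome biogenesis fell (25 of 26 members, mean −0.18, 3 above 0, 0 called, camera adjusted p = 0.000218; adjusted p = 0.595 with an estimated correlation), with the nucleolar genes Nop56 at −0.40 and Ddx21 at −0.56 (−0.08 and −0.31 on their other probe sets). Without replicate 15 its mean was −0.05 (adjusted p = 0.232), and that of the red cell membrane list −0.13 (0.102). The apoptosis and p53 list rose (17 of 20 above 0, mean 0.20, 0 called, 0.00317; adjusted p = 0.119 with an estimated correlation, 0.0772 with the block), with the stress gene Gadd45a at 1.44 and Bcl2l1, which codes for the survival protein BCL-XL, at 0.74 (0.47 with the block). Dimmer Bcl2l1 probe sets gave −0.10, −0.04 and −0.03. The mitosis list rose (19 of 21 above 0, mean 0.20, 0 called, 0.0244; adjusted p = 0.711 with an estimated correlation, 0.629 with the block, mean 0.09), with Ccnb2 at 0.73 and Aurkb at 0.52 (0.48 and 0.22 with the block). Without replicate 14 its mean was −0.05, and without replicate 13 or wild-type replicate 3, 4 or 12 its adjusted p was 0.0732, 0.182, 0.132 and 0.226. With the Gapdh covariate the mitosis p was 0.0792. The apoptosis list gave 0.0665 without replicate 15. Between list scores per array, the exact permutation p was 0.394 for Myc targets, 0.176 for red cell membrane genes, 0.455 for mitosis and 0.0485 for apoptosis. Within the run these were 0.371, 0.0857, 0.686 and 0.257. Of the hematopoietic progenitor genes, Hhex changed by 0.79 (adjusted p = 0.442, and 0.0199 adjusted over the list alone), and that list did not pass (mean 0.13, 0.0568).

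The direct comparison asks how the arrays labelled KLF1-/- KLF2-/- differ from those of KLF1-/-. All KLF1-/- arrays are in the first number run and all those labelled KLF1-/- KLF2-/- in the second. Without the block, an effect of losing KLF2 therefore cannot be told apart from a difference between the runs. With the block, each genotype is measured against the wild-type arrays of its own run. Tcim was lower by −1.80 (SE 0.247, adjusted p = 0.0418), from 8.51 ± 0.43 to 6.71 ± 0.28 (SD, n = 3 each), and was the called gene of 12393, with 74 at an unadjusted p under 0.05 where chance gives 620. With the number run as a block its log2 change was −1.60 (adjusted p = 1.0), and 0 genes were called. The Tcim call was lost in 18 of 23 alternatives, and 0 genes were called with the 6 mutant arrays alone. When single arrays were left out, the call was kept only without KLF1-/- replicate 5. Macrophage and myeloid markers were higher (mean 0.28, 20 of 23 above 0, 0 called, camera adjusted p = 3.33e-09; adjusted p = 0.0954 with an estimated correlation), with Laptm5 at 1.44 and Fcer1g at 0.40. With the block that list had a mean of 0.19 (adjusted p = 0.0168), Laptm5 was 0.20 and Fcer1g 0.27; other Laptm5 probe sets gave −0.09 and −0.01. Higher also were megakaryocyte and platelet genes (0.16, 14 of 22 above 0, 0.0234; adjusted p = 0.104 with an estimated correlation, 0.535 with the block), with Ppbp at 1.28 (0.71 with the block) and Vwf at 0.76. Hematopoietic progenitor genes were higher too (0.12, 14 of 18 above 0, 0.033; adjusted p = 0.265 with an estimated correlation, 0.368 with the block), with Myb at 0.64 and Hlf at 0.30 (0.99 and 0.45 with the block). Dimmer probe sets gave 0.54 and 0.06 for Myb and 0.04 for Hlf. Mesenchyme and mesothelium markers had a mean of 0.16 (18 of 23 above 0, 0.0325; adjusted p = 0.87 with an estimated correlation; mean 0.28 with the block, adjusted p = 0.0253), with Dcn at 0.60 and Lum at 0.45 (0.27 and 0.26 with the block). Myc targets in ribosome biogenesis were lower (mean −0.13, 4 of 25 above 0, 0.0234; adjusted p = 0.87 with an estimated correlation; mean −0.28 with the block, adjusted p = 0.000263), with Nop56 at −0.23 and Polr1a at −0.21 (−0.24 and −0.35 with the block). Other probe sets gave −0.14 for Nop56 and −0.21 and 0.19 for Polr1a. Visceral endoderm markers were lower (mean −0.18, 4 of 23 above 0, 0.033; adjusted p = 0.87 with an estimated correlation), with Foxa2 at −0.23 and Apoa1 at −0.57. With the block that list turned to 0.35 (adjusted p = 0.00102), Foxa2 to 0.08 and Apoa1 to 0.75. Another 5 lists passed with the block and not without it: heme synthesis (−0.36, adjusted p = 0.0109), red cell membrane (−0.24, 0.000881), mitosis (−0.25, 0.0168), erythroid transcription factors (−0.13, 0.0466) and ribosomal proteins (0.18, 0.028). Without the block their means were 0.09, 0.05, −0.03, 0.05 and −0.03. The mean of the visceral endoderm list, without the block, was −0.0164 (adjusted p = 0.847) without KLF1-/- replicate 6 and −0.27 (0.0955) without replicate 8. Without KLF1-/- KLF2-/- replicate 14 or 15 the visceral endoderm adjusted p was 0.387 and 0.103, and the call was lost in 12 of 25 alternatives. It was lost in 14 for the progenitor list, 9 each for the megakaryocyte and mesenchyme lists, 8 for the Myc targets and 2 for the macrophage list. With the Gapdh covariate neither lower list passed (adjusted p = 0.0789 for the Myc targets and 0.138 for visceral endoderm). None of the members of these lists was called singly. Without KLF1-/- replicate 8, 1 list passed, and without KLF1-/- KLF2-/- replicate 13, 2 passed. Without KLF1-/- replicate 6 the Myc target mean was 0.08.

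Both mutant genotypes were set beside each other across all 12393 genes. Their log2 changes correlated at r = 0.616 and rho = 0.467, across genes, which are not independent replicates. Both changes are taken against the same 8 wild-type arrays. In 100 simulations, unchanged groups of 3, 3 and 8 were drawn with replacement from the deviations of all 14 arrays from their genotype means. Unlike in the data, 1 array could then enter more than 1 group. The median r was 0.271, with most values from −0.63 to 0.888. The covariance was 0.0215 against a simulated mean of 0.0123, an excess of 0.00919, and lay within the −0.0403 to 0.0799 of most simulations. With different wild-type arrays for each mutant, over 70 splits, the mean r was 0.195, from −0.168 to 0.469, and with the wild-type arrays of each one's own number run it was 0.208 (rho = 0.0689). Of 5 and 6 genes called lower, 4 were shared: Adcy7, Asb17, Icam4 and Kcnn4. Independent lists of that size would share 0.00242, the simulated median was 0, and 1 of the 100 simulations shared as many. Of 0 and 2 called higher, 0 were shared.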

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

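Chosen after the results were seen were the tests of RNA integrity and genotype for the spread of the arrays, all tests of explanations for the megakaryocyte genes, and for Adcy7 the count without the gene itself and the comparison of its probe sets. The test of neighbouring genes was planned before its own result was known, but after the values of Adcy7 and of a list of Klf1 neighbours had been seen.

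Other splits of the arrays tested whether arrays grouped by chance give as many called genes. Of 100 splits drawn from the 165 of the wild-type and KLF1-/- arrays, the real one included, 5 gave at least the 5 genes of the real split, so chance cannot be excluded, and the highest other split gave 2160. For the arrays labelled KLF1-/- KLF2-/-, 3 of 100 splits gave at least the real 8 genes, a share under the 0.05 set beforehand. These splits ignore the number run, the share was not adjusted for the other comparisons, and the highest other split gave 1434. Chance is therefore argued against only weakly, and 0 genes were called without KLF1-/- KLF2-/- replicate 13 or 14. All arrays so labelled are in the second run, and a difference between runs is not excluded for this count: 4 of the 8 genes were called with the run as a block, and 2 of the 8 within the run. Splits that call so many genes point to a structure of the samples other than genotype. For the direct comparison the 10 splits are too few for a share under 0.05; the real split gave 1 gene and the highest other 0, which counts 1 split as large.

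The arrays spread along 1 component that holds 47.6% of the variance. Unequal ranges of the log2 values are argued against as the whole cause, since quantile normalizing again left 38.2% on the component, and its scores correlated with the earlier ones at 0.995. Genotype is argued against by its share of the variance of the scores, 0.0253. RNA integrity stays open: the 3′ excess of Gapdh correlated with the scores at −0.619, and that of beta-actin at −0.275. No other biological explanation was tested.

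Megakaryocyte and platelet genes were higher in the arrays labelled KLF1-/- KLF2-/-, where a genotype effect is the explanation the design names. A difference between the number runs is argued against only weakly. The score was 0.375 above the wild-type arrays of the same run (exact permutation p = 0.0286), the smallest p that 35 splits give. This list was picked after it had passed camera on these same arrays, and the p was not adjusted over the 32 lists. Hematopoietic progenitor genes, 0.121 higher within the run, reached the same p. The megakaryocyte score rose beyond the endothelial one by 0.26 (exact permutation p = 0.00606), and within the run by 0.201 (p = 0.0286), each the smallest p possible. This argues against endothelial markers rising as much as megakaryocyte genes, but not against endothelial cells in the capture. The endothelial list rose too (mean 0.139, camera adjusted p = 0.00853), and Esm1, secreted by endothelium, was called higher (log2 1.59). Fewer erythroid cells in the capture stay open: against visceral endoderm markers the excess was 0.464 (exact permutation p = 0.188), and within the run 0.178 (p = 0.6). Afp was at 13.62 in wild type and 13.70 in these arrays, and Ttr at 13.82 and 13.83. Both lie near the highest values of the arrays, 14.248 to 14.706, so they do not show that visceral endoderm was unchanged. Of the 23 visceral endoderm markers measured, 8 lay above 0. Macrophages, or mesenchyme and mesothelium, may also contribute, as the excess was 0.192 over macrophage markers (exact permutation p = 0.133) and 0.175 over mesenchyme markers (p = 0.194; within the run 0.0925, p = 0.429).

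Adcy7 was lower in both mutant genotypes, and whether its chromosome segment was carried along with the targeted Klf1 allele cannot be told apart from an effect of genotype. Of 100 measured genes around Klf1, 50 on each side, 4 (4%) differed at an unadjusted p under 0.05 in both comparisons, against 103 of 12292 elsewhere (0.838%, one-sided Fisher's exact p = 0.0109). That count includes Adcy7 itself, and without it 3 of 99 differed (3.03%, one-sided Fisher's exact p = 0.0529). A probe set that measures another transcript stays open too, since another Adcy7 probe set changed by −0.0521 and a dimmer one by −0.714. The mouse strain of the targeted cells is not given in the sources used here.

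In 84 groups of wild-type arrays tested, 52 genes and 32 list scores, 5 held an array far from the others, where chance gives 4.2. Wild-type replicate 9 had the highest Btn1a1, 8.135, with the next at 7.12. Wild-type replicate 11 had the highest Flt1, 7.816, with the next at 7.666. Wild-type replicate 3 had the lowest Hhex, 7.009, with the next at 7.686. Wild-type replicate 4 had the lowest Pf4, 10.43, with the next at 11.07, and the lowest Vwf, 4.808, with the next at 5.429.

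Of 22626 probe sets, 2246 are not paired with a single gene and entered no comparison of genes. In a fit of all probe sets, 1 that the annotation pairs with no gene changed by −4.82 in KLF1-/- (SE 0.226, adjusted p = 9.18e-08) and by −4.88 in the arrays labelled KLF1-/- KLF2-/- (adjusted p = 7.91e-08). It ran from 12.7 to 13.4 on the wild-type arrays and from 7.64 to 8.74 on the mutant arrays.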

How the results depend on the processing

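Added after the data were examined were the fits with principal components as covariates, without the arrays at the ends of the first component, quantile normalized again with the number run as a block, with array weights under a strong prior, and, for lists and named genes, quantile normalized again, and for named genes, 1 number run alone. No paired analysis was possible because the sources used here do not say which arrays share a litter. The signal over background of an array limits dim genes, and the number of arrays limits precision. Where a value moved, the cause was not tested, except that fits of fewer arrays have less precision.

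The 5 genes of KLF1-/- became 3 with the number run as a block, 2 with the ribosomal protein median made equal, 353 with array weights, 9 with weights under a strong prior, 32 with 2 principal components as covariates, 1 without the arrays at the ends of the first component, and 0 (252 at an unadjusted p under 0.05) with 1 number run alone. Leaving out 1 array gave 1 to 6. The 8 genes of KLF1-/- KLF2-/- (2 higher, 6 lower) became 2 with the mean of all probe sets, 5 (3 higher, 2 lower) with the ribosomal protein median made equal, 2347 (1317 higher, 1030 lower) with array weights, 42 (23 higher, 19 lower) with the strong prior, 83 (37 higher, 46 lower) with principal components, and 3 with 1 number run alone. With every probe set tested, 5 probe sets were called, 1 of them paired with no gene. Leaving out 1 array gave 0 to 8. The count stayed within 1.5 times on quantile normalizing again (12, of which 6 higher and 6 lower) and with the block (7, 0 higher). The 1 gene of the direct comparison became 0 with the block, a common median, the ribosomal protein median, the Gapdh covariate, every probe set, without the arrays at the ends of the first component, quantile normalized with the block, and with the 6 mutant arrays alone, 6029 with array weights, and 0 to 1 without 1 array. The array weights were degenerate, with 58.7 on KLF1-/- KLF2-/- replicate 13 and 10.6 on KLF1-/- replicate 8, so the counts they give say nothing about genotype.

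The correlation of 0.616 between mutant changes became 0.208 with the block and 0.208 with 1 number run alone, and 0.344 to 0.666 without 1 array, lowest without KLF1-/- replicate 6. The 0 genes called between the wild-type arrays of the number runs became 0 to 2 without 1 array, with 2 without replicate 4. The 6 lists of KLF1-/- became 2 with the block, 2 quantile normalized with the block, 1 with an estimated correlation, 0 with fry, and 3 to 8 without 1 array. The 8 lists of KLF1-/- KLF2-/- became 1 with an estimated correlation, 1 with fry and 7 to 13 without 1 array. The 6 lists of the direct comparison became 3 with the mean of all probe sets, 0 with an estimated correlation, 0 with fry and 1 to 9 without 1 array.

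Among called results, the megakaryocyte list of KLF1-/- KLF2-/- passed in all 25 alternatives run for it (mean 0.296 to 0.506), and that of KLF1-/- in 24 (0.151 to 0.309). In KLF1-/-, of 24 alternatives, Adcy7 was called in 22, Asb17 in 21, Kcnn4 in 17, Plek2 in 15 and Icam4 in 9. In KLF1-/- KLF2-/-, Asb17 was called in 22, Kcnn4 in 19, Tcim in 18, Btn1a1 in 14, Adcy7 in 13, Pklr in 12, Icam4 in 11 and Esm1 in 8. Tcim in the direct comparison was called in 5 of 23. These counts for genes include the fit with the degenerate array weights, which kept every one of these calls. They also include 14 fits that left out 1 array and share most of their data, so they are not independent checks. Of 25 alternatives, the calls of other KLF1-/- lists were lost in 13 (macrophage), 11 (globins), 8 (mitosis), 7 (iron) and 4 (red cell membrane), and those of KLF1-/- KLF2-/- in 13 (mitosis), 5 (apoptosis), 4 (macrophage) and 3 each (red cell membrane, Myc targets, mesenchyme, endothelial). The called genes kept their direction in every alternative run for them.

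Some directions turned. The mitosis list turned to −0.138 in KLF1-/- without the arrays at the ends of the first component and −0.0643 without KLF1-/- replicate 6 (up to 0.388 without 1 array, replicate 8), and in KLF1-/- KLF2-/- to −0.0532 without its replicate 14 (up to 0.47, without 15). In the direct comparison, the Myc target list turned to 0.0839 without the end arrays and without KLF1-/- replicate 6 alone, and was 0.00049 without KLF1-/- KLF2-/- replicate 15 (lowest −0.311, without KLF1-/- replicate 5). Visceral endoderm markers turned to 0.349 with the block and 0.241 quantile normalized with the block. Klf2 in KLF1-/- was 0.02037 and 0.001488 without wild-type replicate 1 and 3, and 0.08899 and 0.01074 without KLF1-/- replicate 5 and 8 (lowest −0.1848, without replicate 6). Hbb-y in KLF1-/- was 0.01831 quantile normalized again, 0.04653 with the block as well, and 0.0143 without KLF1-/- replicate 5 (lowest −0.08326, without replicate 6). With array weights, Klf1 was 0.2246 and Hlf −0.04113 in the direct comparison, Ccnb2 −0.1132 in KLF1-/-, and Flt4 −0.02075 in KLF1-/- KLF2-/-. Foxa2 in the direct comparison was 0.08097 with the block, 0.2048 with weights and 0.1116 quantile normalized with the block, and Apoa1 0.7491, 0.1472 and 0.5531.

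For the counts, correlation and numbers of lists together, 130 alternatives left the result on its side, 52 weakened it, 9 strengthened it and 5 moved it. For single genes and lists, 2022 left it, 254 weakened, 80 strengthened and 24 turned it.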

Other observations

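The permutation tests of list scores here were chosen after the data were examined; the camera tests were not. Of the 32 gene lists, 20 passed in none of the comparisons without the number run as a block, with camera adjusted p from 0.069 to 0.997. Their mean log2 changes are given for KLF1-/- and then for KLF1-/- KLF2-/-. Among erythroid lists, heme synthesis and globin chaperone genes had −0.0662 and 0.0248, erythroid transcription factors 0.0272 and 0.0789, erythropoietin and KIT signalling 0.0808 and 0.101, and organelle clearance 0.0769 and 0.0952. With the number run as a block, heme synthesis turned to 0.159 and −0.201 (camera adjusted p = 0.189 and 0.0609). Erythroid transcription factors then had 0.12 and −0.0139, and the other erythroid lists named here kept their sign. The Krüppel-like family had −7.33e-05 and −0.0291, with medians of 0.0927 and 0.0952, so that mean and median differ in sign. G1 to S regulators had 0.0646 and 0.122, and DNA replication genes 0.104 and 0.14. Myc and its partners had 0.0136 and −0.00194, and Myc targets in metabolism 0.0496 and −0.0181. Ribosomal proteins had 0.0253 and −0.00822, and translation factors 0.046 and 0.00993.

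Among stress and metabolic lists, antioxidant genes had means of 0.0582 and 0.108, hypoxia and glycolysis genes 0.086 and 0.045, cholesterol synthesis genes 0.0742 and 0.111, heat shock and unfolded protein response genes 0.0906 and 0.176, and interferon response genes −0.0536 and −0.0197. Endothelial targets of KLF2 had 0.0462 and −0.0132, and mast cell markers −0.0614 and −0.0314. Neighbours of Klf1 had 0.0159 and −0.0329, and those of Klf2 0.0749 and 0.0765. Of the lists that passed elsewhere, in KLF1-/- the apoptosis list had 0.161, mesenchyme markers 0.0594, progenitor genes 0.00912 and Myc targets in ribosome biogenesis −0.0477, and none of them passed there. For globins in KLF1-/- KLF2-/- the mean of −0.302 and the median of 0.0239 differ in sign. In KLF1-/- the medians of erythroid transcription factors (−0.0247) and progenitor genes (−0.0429) also differ in sign from the means. In KLF1-/- KLF2-/- so do those of Myc and its partners (0.0413), ribosomal proteins (0.000257), translation factors (−0.00617) and mast cell markers (0.0278).

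Between the wild-type arrays of the number runs, visceral endoderm markers were −0.526 and heme synthesis genes 0.453 in replicates 9 to 12 minus 1 to 4 (exact permutation p = 0.143 each, adjusted p = 0.914 over 32 lists). Visceral endoderm scores differed from all wild-type arrays by 0.111 in KLF1-/- and −0.0656 in KLF1-/- KLF2-/-, and from those of the same number run by −0.152 and 0.197 (exact permutation p = 0.733, 0.842, 0.686 and 0.457).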
